A study of Mus musculus with 18 samples.

How the data were processed

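RNA of mouse embryonic stem cells (F1 of C57Bl6N and 129Sv) of the genotypes Pax7+/+ and Pax7-/- was measured on 18 Affymetrix arrays, 3 per genotype at day 0 (undifferentiated cells with LIF), day 7 (embryoid bodies) and day 21 (embryoid body outgrowths, without LIF and with retinoic acid and ITS). The deposited values are log2 intensities per probe set, summarised by the authors with RMA, and the submitters' notes name RMA and Partek without version or order. The arrays fell into 2 sets with different spread, and the labels do not say whether they come from 1 joint summary. Samples were grouped by genotype and day from the labels, and the replicate numbers were not used to pair samples: with the array set removed, arrays of 1 number and day correlated between -0.22 and 0.23.

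Of 41345 probe sets, 23521 carried 1 gene symbol, 1814 several and 16010 none. For each gene the probe set with the highest mean over all arrays was kept, which gave 22180 genes, of which 1082 had several probe sets. No gene was left out for low signal. Gene identifiers matched the reference annotation for 21994 genes, and 21991 had a chromosome. The reference gives gene positions on the assembly GRCm38.p6. The neighbourhood of Pax7 was planned as the genes within 10 Mb. The 50 genes on each side were run first by mistake, and their result was seen before the planned set of 318 genes was put in its place; both are given.

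Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes without trend). As fixed before the data were examined, the fit had 6 group means and no block, with 12 residual degrees of freedom, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05, with the count at 2-fold or more beside it. The array set as a fixed block, with 11 residual degrees of freedom, was added after the sets had been seen, as were fits to the narrow arrays (4 residual degrees of freedom) and the wide arrays (2) alone. The 10 comparisons were Pax7-/- against Pax7+/+ at each day, the steps from day 0 to day 7 and from day 7 to day 21 within each genotype, and the change of the genotype difference over each step and from day 0 to day 21. For arrays their number limits the precision: 3 arrays against 3 cannot give an exact permutation p below 0.1.

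The 38 gene lists were written before the data were examined. The 37 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Chromosomes were tested in the same way, and their medians were taken over genes above the 75th percentile of mean value. Genes were named by a rule fixed in advance: per genotype comparison the 10 largest rises and 10 largest falls among genes that passed, changed at least 2-fold and did not overlap between the groups' arrays, 5 each way per step and per change of the genotype difference, and up to 4 passing members of a list, or up to 2 where none passed. Symbols of predicted genes were passed over. The rule was applied again to the fit with the array set as a block, and overlap was then read within each set. For a change of the genotype difference the same sign in both sets was asked in place of no overlap.

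The code was tested on simulated normal values with the mean of each gene in each array set and its residual spread, to which known changes were added. Of genes moved by 2 log2, 38.5%, 52.7% and 57.4% were recovered at days 0, 7 and 21 without the block, and 100%, 100% and 98.5% with it. With the block these were 90%, 79.7% and 77.8% at 1 log2, and 35.4%, 22.8% and 25.6% at 0.5 log2. Each change was the same on narrow and wide arrays, as the fit with the block assumes. Recovery of genes whose change differs between the sets was therefore not tested. Alternatives covered quantile normalization and median centring, filters at the 25th percentile and at the median, other summaries per gene, other limma options, a replicate block, thresholds, and leaving out each array. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.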

Results

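Mouse embryonic stem cells with (Pax7+/+) and without (Pax7-/-) a working Pax7 gene were compared as undifferentiated cells at day 0, as embryoid bodies at day 7 and as outgrowths at day 21. Pax7 encodes a paired box transcription factor of muscle satellite cells and of the neural crest. Each genotype and day had 3 arrays, and the question was which genes differed between genotypes and which changed as the cells differentiated. The probe set for Pax7 gave group means between 5.38 and 5.77 log2, against array medians of 4.55 to 4.97 log2. Pax7-/- minus Pax7+/+ came to 0.03, 0.35 and -0.10 log2 at days 0, 7 and 21. With the array set described next as a block, these differences were 0.03 ± 0.23, -0.01 ± 0.24 and 0.25 ± 0.24 log2 (SE), with adjusted p = 0.98, 0.997 and 0.681. Where the probes lie relative to the altered part of the gene is not given, so the Pax7 reading checks no label.

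The arrays fell into 2 sets by the spread of their values. In 10 arrays, called narrow here, the standard deviation over probe sets was 1.37 to 1.45 log2, and in the other 8, called wide, it was 1.79 to 1.85. Pearson correlations over probe sets were 0.914 or higher within a set and 0.653 to 0.789 between sets, genes not being independent replicates. All 6 groups held arrays of both sets, and the first principal component, with 79.7% of the variance, separated the sets. After each gene was centred within each set, all 18 arrays matched best, in the other set, an array of their own genotype and day. With the set removed, the first component held 38.1% of the variance and set the day 0 arrays (-51.3 to -16.8) apart from those of day 7 (0.434 to 11.1) and day 21 (9.05 to 50), as the plot of principal components shows. Days 7 and 21 overlapped there, by 1 Pax7-/- array of each. The sets still differed on this component: at day 0 the wide arrays read -51.3 and -49.5 and the narrow ones -25.3 to -16.8. At day 21 wide arrays read 29.1 to 50 and narrow ones 9.05 to 20.7, and at day 7 the sets overlapped.

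**Figure D1:**
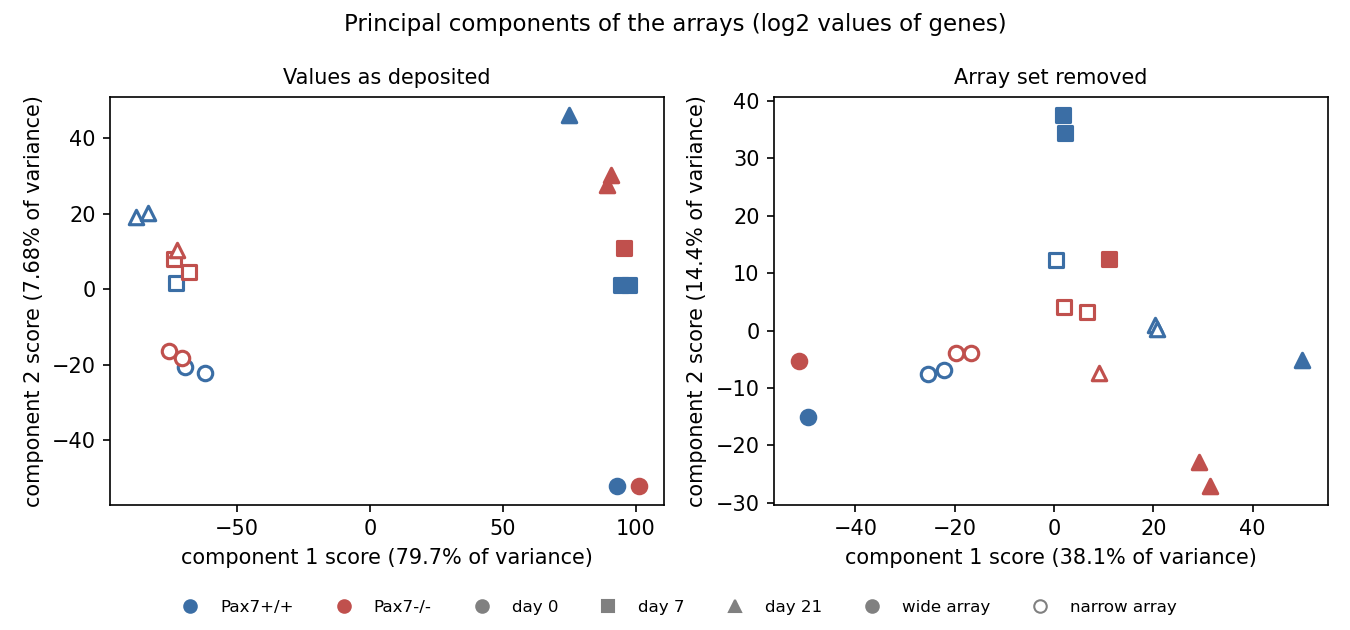
Scores of the 18 arrays on principal components 1 and 2, for the values as deposited (left) and after removal of the array set (right); each point is 1 array, colour gives genotype, shape gives day, and filled or open points are wide or narrow arrays. Component 1 separates the array sets in the deposited values (79.7% of the variance) and day 0 from the later days once the set is removed (38.1%). On the right the wide arrays of days 0 and 21 still lie further out on component 1 than the narrow ones.

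The test fixed before the data were examined had 6 group means and no block, and limma called 0 of 22180 genes between genotypes at each of the 3 days. At an unadjusted p under 0.05 it gave 167, 278 and 539 genes at days 0, 7 and 21. With the array set as a block, a fit chosen after the sets were seen, 284, 139 and 1085 genes differed between genotypes, of which 68, 37 and 178 differed at least 2-fold. Each set held 1 or 2 arrays per group, too few for tests within a set to support these counts. Over all genes the sign of the difference agreed between the sets for 57.3%, 56.5% and 60.2%. Of the gene lists, camera called 8, 9 and 16 with the block and 7, 15 and 16 without it, of which 6, 7 and 14 were called with both and in the same direction. At day 0 the 8 became 5 when any 1 of the Pax7+/+ replicates was left out. The 7 became 22 without Pax7+/+ replicate 3, and 11, 16 and 12 without Pax7-/- replicates 1, 2 and 3. The gene values below come from the fit with the block unless another is named. The p-values measure only the spread between samples labelled as biological replicates, which with the block includes disagreement between the sets. The fit with the block gives each gene 1 difference for both sets, although for some genes its size differed between them. On narrow and wide arrays at day 0 Cubn read 1.37 and 2.82, Emilin2 -1.22 and -2.90, and Ptgs2 -2.73 and -1.39. Tmem64 read 2.28 and 2.26 there. From day 0 to day 7 in Pax7-/- Fabp7 changed by 2.15 and 5.19.

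In the undifferentiated cells at day 0, Pax7-/- cells held more RNA of Lama1, a chain of the basement membrane protein laminin, than Pax7+/+ cells did. The difference was 2.38 ± 0.20 log2 (SE, n = 3 per genotype, adjusted p = 1.82e-05), or 5.22-fold. Tmem64 (2.27 ± 0.12), the zinc finger gene Zfp296 (2.17 ± 0.27) and Srgn, which encodes the proteoglycan serglycin (2.07 ± 0.16), were higher by similar amounts. Cubn, the endocytic receptor cubilin of visceral endoderm, was higher by 1.85 ± 0.43, and Slc7a6, Stag3, Spry4, Arhgap6 and Epha4 by 1.34 to 1.58. Lower in Pax7-/- were Ptgs2, the inducible cyclooxygenase (-2.28 ± 0.33, adjusted p = 0.0022), the chemokine gene Ccl2 (-2.02 ± 0.44), the stress gene Chac1 (-1.87 ± 0.29) and Emilin2 (-1.78 ± 0.30). Septin1, Cth, Mid1, Reep6, the matrix gene Tnc and the phosphatase gene Dusp1 were lower by -1.59 to -1.46. In all, 86 genes were higher and 198 lower.

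Genes of parietal endoderm, the cells that lay down the laminin-rich Reichert's membrane, were higher in Pax7-/- at day 0 by camera (adjusted p = 0.00427, and adjusted p = 0.337 with an estimated correlation). Of 15 measured, 4 were higher, 0 lower and 11 did not pass (adjusted over the list alone, 4 higher and 3 lower), with Gata6 at 1.26 ± 0.27, Lamb1 at 1.00 ± 0.22 and Sparc at 0.53 ± 0.12 beside Lama1. Immediate early and stress genes were lower, with Chac1, Dusp1, Fos (-1.33 ± 0.29) and Egr1 (-0.56 ± 0.13) passing among 17 and 13 not passing (adjusted over the list alone, 1 higher and 7 lower; adjusted p = 0.00102, and adjusted p = 0.337 with an estimated correlation). Fibroblast and extracellular matrix genes were also lower, with a median of -0.42 log2. Of 21 measured, Fn1 (-1.05 ± 0.22) passed and 20 did not (adjusted over the list alone, 0 higher and 3 lower). By camera the list had adjusted p = 1.34e-05, and adjusted p = 0.506 with an estimated correlation. The cell types in each culture were not measured. A difference in the share of fibroblasts therefore cannot be told from a difference within the stem cells.

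The interferon response list was lower in Pax7-/- at day 0, with Usp18 (-1.45 ± 0.31) passing among 16 (adjusted over the list alone, 0 higher and 4 lower; adjusted p = 0.00102, and adjusted p = 0.506 with an estimated correlation). Genes of the 2-cell-like state were higher, none of the 11 passing alone (adjusted over the list alone, 2 higher; adjusted p = 0.00614, and adjusted p = 0.966 with an estimated correlation). Zscan4d, the largest by test among them, read 1.64 ± 0.40 with adjusted p = 0.0625. The germ line list was higher, with Stag3, a cohesin subunit of meiosis, passing among 12 (adjusted over the list alone, 1 higher), and the mitosis and the hypoxia and glycolysis lists were lower, each with adjusted p = 0.0477, and adjusted p = 0.966 with an estimated correlation. Vegfa (-0.95 ± 0.13) passed in the hypoxia list of 14 (adjusted over the list alone, 0 higher and 2 lower) and no gene in the mitosis list of 20 (adjusted over the list alone, 1 higher and 6 lower). After quantile normalization the mitosis and hypoxia lists did not pass (adjusted p = 0.408 and 0.15), nor without the block (adjusted p = 0.545 and 0.159). After median centring the germ line, hypoxia and mitosis lists did not pass (adjusted p = 0.0503, 0.0503 and 0.0536). Leaving out 1 array at a time gave 120, 167 and 184 genes at day 0 without Pax7+/+ replicates 1, 2 and 3, and 145, 155 and 152 without Pax7-/- replicates 1, 2 and 3.

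In embryoid bodies at day 7, the imprinted genes Rian and Mest and the mesenchymal cadherin gene Cdh11 were higher in Pax7-/- by 1.69 ± 0.25, 1.43 ± 0.26 and 1.58 ± 0.17 log2 (SE, n = 3 per genotype), or 3.22-, 2.70- and 2.99-fold, with adjusted p = 0.00725, 0.0236 and 0.0022. The myosin light chain gene Myl9 (1.33 ± 0.22), Ccn1 (1.21 ± 0.20) and the matrix protease gene Mmp2 (1.2 ± 0.17) were higher as well. Herpud1, Rpl3, Lamtor3-ps and Adam23 were higher by 1.17 to 1.29. Lower in Pax7-/- were Pramel20 (-2.63 ± 0.38), Tmem92 (-1.56 ± 0.23) and Zfp352 (-1.41 ± 0.30). The water channel gene Aqp3 (-1.34 ± 0.26), the connexin gene Gjb5 (-1.22 ± 0.20), the claudin gene Cldn4 (-1.17 ± 0.16) and Plet1 (-1.21 ± 0.17) were lower too. Igf2r, the imprinted receptor that clears Igf2, and the fatty acid desaturase genes Scd1 and Scd3 were lower by -1.28 to -1.18. In all, 71 genes were higher and 68 lower.

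Naive pluripotency genes were lower in Pax7-/- at day 7, with a median of -0.46 log2. Of 26 measured, Fbxo15 (-0.78 ± 0.13) and Sall4 (-0.56 ± 0.11) passed and 24 did not (adjusted over the list alone, 0 higher and 7 lower; adjusted p = 1.34e-08, and adjusted p = 0.193 with an estimated correlation). The 2-cell-like list had a median of -0.72 and Zfp352 as its passing gene of 11, and 10 genes were lower when adjusted over the list alone (adjusted p = 5.03e-09, and adjusted p = 0.177 with an estimated correlation). Trophoblast genes were lower with 0 of 12 passing (adjusted over the list alone, 4 lower; adjusted p = 0.000891, and adjusted p = 0.202 with an estimated correlation). Smooth muscle genes were higher, with the calponin gene Cnn1 (0.81 ± 0.17) passing among 11 (adjusted over the list alone, 2 higher; adjusted p = 0.000891, and adjusted p = 0.193 with an estimated correlation). Immediate early genes, lower at day 0, were higher at day 7, with Atf3 (0.71 ± 0.14) and Egr1 (0.61 ± 0.13) passing among 17 (adjusted over the list alone, 4 higher and 1 lower; adjusted p = 6.44e-05, and adjusted p = 0.17 with an estimated correlation). Without the block this list did not pass at day 7 (adjusted p = 0.721).

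Fibroblast genes were higher in Pax7-/- at day 7 as a list, with 0 of 21 passing, adjusted over the list alone included (adjusted p = 0.00323, and adjusted p = 0.722 with an estimated correlation). The mitosis list was lower with 0 of 20 passing (adjusted over the list alone, 1 lower; adjusted p = 0.00138, and adjusted p = 0.424 with an estimated correlation). The list of cell cycle brakes and p53 targets was higher with 0 of 17 passing (adjusted over the list alone, 4 higher and 1 lower; adjusted p = 0.0182, and adjusted p = 0.177 with an estimated correlation). Without the block its direction was lower and it did not pass (median -0.08 against 0.13 log2 with the block, adjusted p = 0.32). Called without the block and not with it at day 7 were DNA replication, parietal endoderm, hypoxia and retinoic acid genes, all lower, and neural progenitor, cardiac muscle, sarcomere and paraxial mesoderm genes, all higher. These 8 lists had adjusted p between 0.000214 and 0.0459, and adjusted p = 0.722 with an estimated correlation. The count of 139 genes rested on single arrays: it was 242, 21 and 25 without Pax7+/+ replicates 1, 2 and 3, and 37, 46 and 26 without Pax7-/- replicates 1, 2 and 3.

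In the day 21 outgrowths, Sox1, a transcription factor of the neural plate, was higher in Pax7-/- by 1.76 ± 0.26 log2 (SE, n = 3 per genotype, adjusted p = 0.000967), or 3.39-fold, and Prtg, which encodes protogenin of the early neural tube, by 1.87 ± 0.48. The nucleolar and ribosomal genes Rpl3 (1.74 ± 0.23), Npm1 (1.61 ± 0.25) and Abce1 (1.51 ± 0.25), the mitochondrial gene C1qbp (1.65 ± 0.16) and the linker histone gene H1f5 (1.60 ± 0.17) were higher too. Cyb5b, Irs4 and Tmem47 were higher by 1.54 to 1.62. Lower in Pax7-/- were the genes of the secreted proteins Chil1 (-2.25 ± 0.48) and Saa3 (-2.13 ± 0.51), the hypoxia factor gene Epas1 (-1.66 ± 0.17), Emp2 (-1.59 ± 0.22) and the basement membrane gene Nid1 (-1.52 ± 0.36). The imprinted genes Igf2r (-1.77 ± 0.19), Cdkn1c (-1.52 ± 0.29) and Grb10 (-1.47 ± 0.29) were lower, as were Plet1 and Creb3l1 (-1.42 ± 0.17 and -1.32 ± 0.19). In all, 847 genes were higher and 238 lower.

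Genes of DNA replication were higher in Pax7-/- at day 21 as a group. Of 19 measured, 12 were higher, 0 lower and 7 did not pass (adjusted over the list alone, 15 higher), with Mcm5 at 1.36 ± 0.18, Pcna at 0.99 ± 0.15 and Mcm7 at 0.95 ± 0.18, and the list had adjusted p = 2.02e-16, and adjusted p = 0.00409 with an estimated correlation. Mitosis genes followed, 8 of 20 being higher, 0 lower and 12 not passing (adjusted over the list alone, 15 higher; adjusted p = 3.07e-12, and adjusted p = 0.0327 with an estimated correlation). Top2a came to 1.13 ± 0.14 and Ccnb2 to 0.97 ± 0.18. Ribosomal protein genes were higher in 8 of 15 cases and lower in 0, with 7 not passing (adjusted over the list alone, 10 higher; adjusted p = 5.51e-09, and adjusted p = 0.00409 with an estimated correlation). Rpl19 came to 1.09 ± 0.18 and Rpl7 to 0.77 ± 0.17. Parietal endoderm genes, higher at day 0, were lower at day 21. Of 15, 6 were lower, 0 higher and 9 did not pass (adjusted over the list alone, 8 lower; adjusted p = 8e-09, and adjusted p = 0.00628 with an estimated correlation). Lamb1 came to -1.32 ± 0.22, Lama1 to -1.22 ± 0.20 and Serpinh1 to -0.94 ± 0.14 beside Nid1.

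At day 21 Sox1, Otx1 (1.21 ± 0.34) and Sox3 (0.98 ± 0.27) were the 3 genes of 20 neural progenitor genes that passed, all higher (adjusted over the list alone, 12 higher; adjusted p = 2.24e-06, and adjusted p = 0.336 with an estimated correlation). Primed epiblast genes were higher in 5 of 12 cases and lower in 0 (adjusted over the list alone, 6 higher; adjusted p = 0.000341, and adjusted p = 0.086 with an estimated correlation). The DNA methyltransferase gene Dnmt3b came to 1.41 ± 0.20, Zic2 to 1.32 ± 0.17, Otx2 to 1.24 ± 0.27 and Pou3f1 to 1.01 ± 0.18. Notch pathway genes Lfng (1.09 ± 0.25), Jag1 (1.03 ± 0.17) and Notch1 (0.43 ± 0.11) were higher among 14 (adjusted over the list alone, 3 higher; adjusted p = 0.000516, and adjusted p = 0.316 with an estimated correlation). Neuron genes Stmn2, Ina and Tubb3 were higher by 0.74 to 0.88 among 21 (adjusted over the list alone, 3 higher; adjusted p = 0.00783, and adjusted p = 0.335 with an estimated correlation, and adjusted p = 0.0663 without the block). Among 26 naive pluripotency genes, Utf1 (1.45 ± 0.28), Sox2 (1.41 ± 0.21) and Nanog (1.37 ± 0.33) were higher with 1 other gene, and Klf4 was lower (-1.2 ± 0.16), and the list as a whole did not pass (adjusted over the list alone, 5 higher and 1 lower; adjusted p = 0.596, and adjusted p = 0.00802 without the block).

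The visceral endoderm and liver list was lower in Pax7-/- at day 21, with a median of -0.62 log2 (-0.26 on narrow and -1.23 on wide arrays). Dab2 (-0.88 ± 0.15) passed among 24 (adjusted over the list alone, 1 lower). By camera the list had adjusted p = 1.96e-07, and adjusted p = 0.336 with an estimated correlation. In the fibroblast list Pdgfra (-1.26 ± 0.30), Dcn (-1.25 ± 0.31) and Col5a1 (-0.84 ± 0.20) were lower among 21 (adjusted over the list alone, 4 lower; adjusted p = 0.000623, and adjusted p = 0.364 with an estimated correlation). Fosb (-1.10 ± 0.25) and Atf3 (-0.69 ± 0.14) were lower among 17 immediate early genes (adjusted over the list alone, 3 lower; adjusted p = 0.0201, and adjusted p = 0.306 with an estimated correlation). Without the block that list was in the other direction and did not pass (median 0.07 against -0.19 log2 with the block, adjusted p = 0.663). The blood, Hox and trophoblast lists were lower and the Wnt target list higher, with 0 genes passing in each and 2, 0, 0 and 3 adjusted over the list alone (adjusted p = 0.0123, 0.0262, 0.049 and 0.0303, and adjusted p = 0.528, 0.652, 0.423 and 0.306 with an estimated correlation). Hox and trophoblast genes did not pass as lists after quantile normalization (adjusted p = 0.0611 and 0.0586). Leaving out 1 array gave 659 to 972 genes at day 21, with 659 and 707 without Pax7-/- replicates 3 and 2.

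Muscle genes, which the study of Pax7 brings to mind, gave different answers with and without the block. With it, the lists of myogenic regulators (22 genes), skeletal muscle sarcomere (29) and paraxial mesoderm (25) had adjusted p between 0.427 and 0.953 at the 3 days. Without it, in the fit fixed in advance, the sarcomere list was higher in Pax7-/- at day 7 (median 0.26 log2, adjusted p = 0.00454), and so was the paraxial mesoderm list (median 0.20, adjusted p = 0.0459), both with adjusted p = 0.722 with an estimated correlation. With the block these medians were 0.03 and -0.06. At day 7 the sets were uneven, with 1 narrow and 2 wide Pax7+/+ arrays against 2 narrow and 1 wide Pax7-/- arrays. Within the narrow and the wide arrays the sarcomere medians were -0.04 and -0.03 and the paraxial mesoderm medians 0 and -0.03. Neither set alone thus showed the rise seen without the block. Of these genes, Mef2d (-0.60 ± 0.11) was lower and En1 (0.84 ± 0.22) and Lfng higher in Pax7-/- at day 21, and none passed at days 0 and 7. From day 7 to day 21 in Pax7-/- the sarcomere list rose with 0 of 29 passing, adjusted over the list alone included (adjusted p = 0.000991, and adjusted p = 0.241 with an estimated correlation), and in Pax7+/+ it had adjusted p = 0.0629. Without the block these were adjusted p = 0.774 and 0.000637. From day 0 to day 7 in Pax7+/+ the sarcomere list was lower without the block (median -0.31 log2, camera, adjusted p = 0.00133). With the block it did not pass there (adjusted p = 0.538). Of the 8 other measured Pax genes, 0 passed between genotypes with limma at any day. Primitive streak, endothelium, neural crest, cartilage and bone, keratinocyte and X inactivation lists did not pass in any of the 10 comparisons, with adjusted p between 0.135 and 0.999. The mitochondrial list had 0 measured genes and was not tested. The plot of gene list medians gives these lists beside the differentiation steps where any of them passed.

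**Figure D2:**
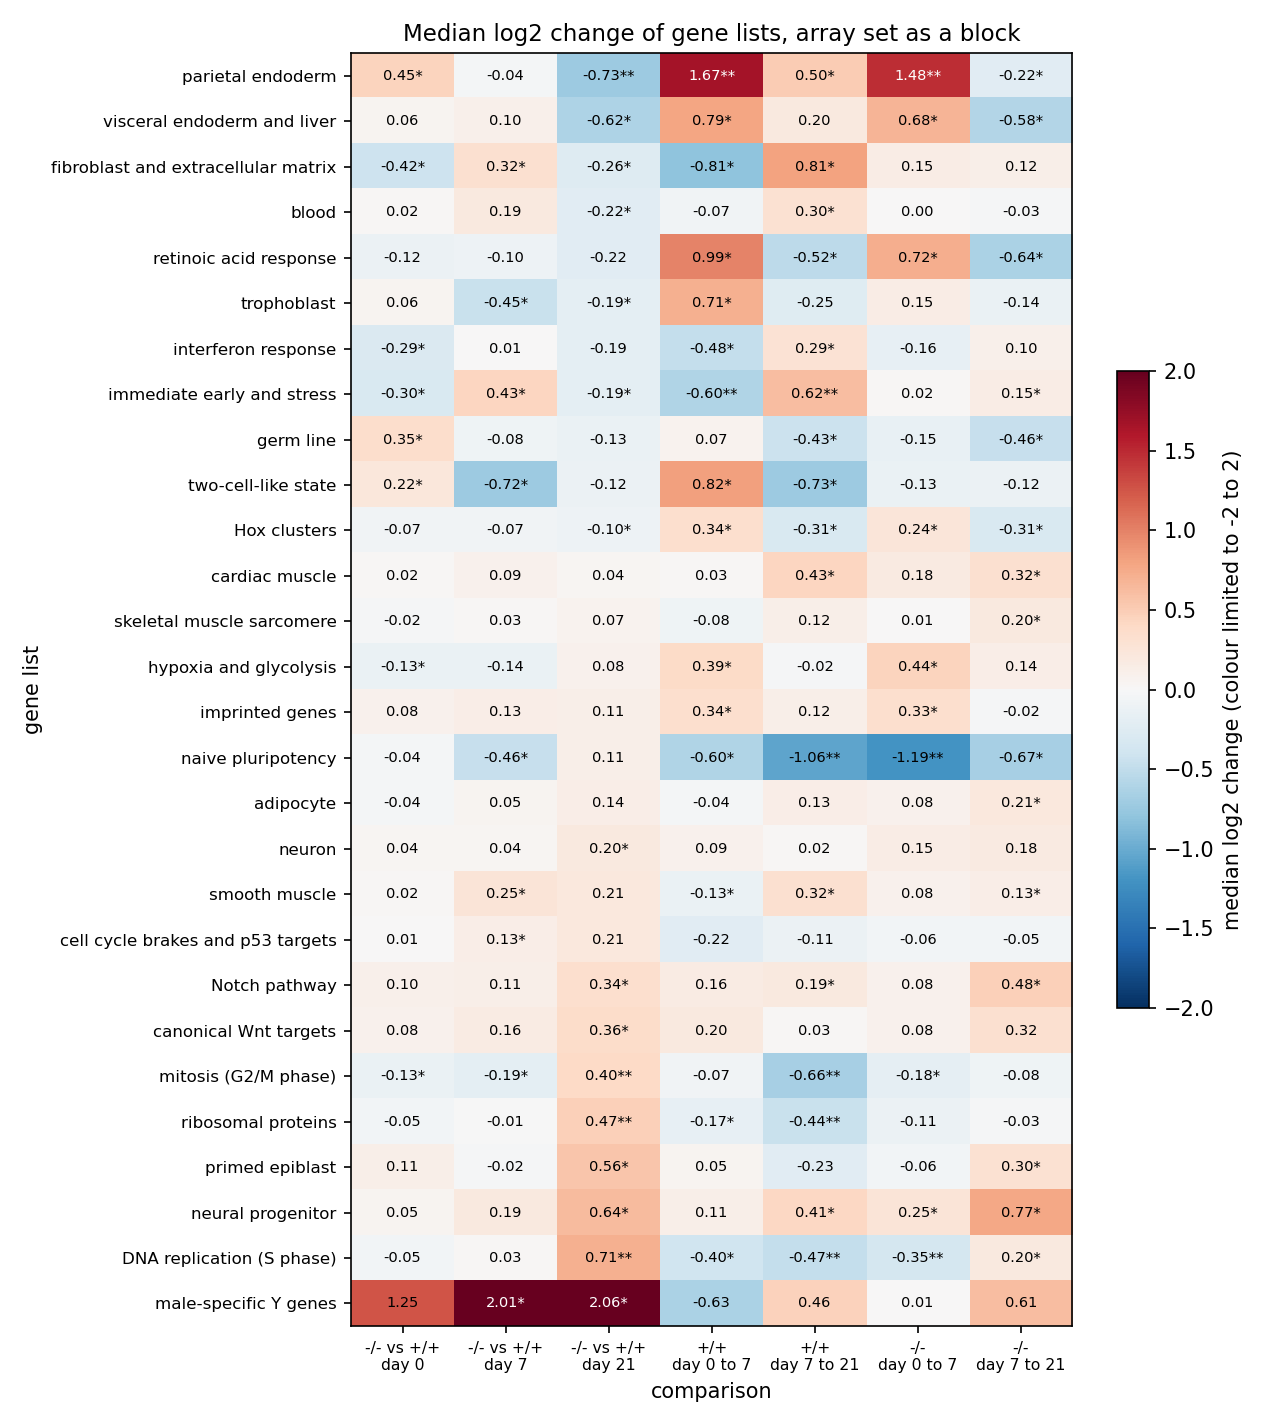
Median log2 change of the genes of each list that passed camera in at least 1 of the 7 comparisons, with the array set as a block; red is higher in the group named first or later in time, 1 asterisk marks adjusted p under 0.05 and 2 asterisks the same with an estimated correlation. DNA replication genes stood 0.71 log2 higher and parietal endoderm genes lower, at -0.73 log2, in Pax7-/- at day 21.

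Across the days, 9 genes differed in the same direction at all 3, 5 higher in Pax7-/- and 4 lower, where independent lists would share 0.011 and 0.0065. The 3 lists come from 1 fit with the same spread per gene and are not independent, so no excess can be read from this. Higher were Mest, with 1.24, 1.43 and 1.45 log2 at days 0, 7 and 21, Aatf (0.74, 0.75 and 0.81), Usp22 (0.74, 0.59 and 0.56), Otud4 (0.60, 0.61 and 0.45) and Pdpr (0.49, 0.49 and 0.45). Lower were Cyb5r3 (-1.18, -1.08 and -0.85), the small nucleolar RNA gene Snora73b (-1.16, -1.43 and -0.83) and the lysosomal enzyme genes Ctsa (-0.85, -0.76 and -0.91) and Hexa (-0.80, -0.68 and -0.81). These 9 were named because they are few, after their values were seen. Their number was 3 without Pax7+/+ day 7 replicate 2 or 3 or Pax7-/- day 7 replicate 3, 4 without Pax7-/- day 7 replicate 1 or 2 and 5 without Pax7-/- day 0 replicate 3. Of the 5 higher genes, 4 lie on chromosomes 8 and 11. With genes of these chromosomes left out, 1 gene was higher and 4 were lower at all 3 days. Without the block 0 genes were shared, and no gene passed at any day in limma.

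Genes of chromosomes 8 and 11 were higher in Pax7-/- at each day. Among genes above the 75th percentile of mean log2 value, 364 on chromosome 8 and 510 on chromosome 11, the median stood above that of the other chromosomes by 0.23 and 0.24 log2 at day 0, 0.28 and 0.30 at day 7, and 0.29 and 0.28 at day 21. With camera the 2 chromosomes had adjusted p = 0.000307 and 0.000277 at day 0, 5.08e-09 and 8.06e-08 at day 7, and 9.7e-07 and 6.56e-05 at day 21. With an estimated correlation these were adjusted p = 0.136 and 0.131, 0.00996 for both, and 0.0527 for both. Without the block the calls rested on single arrays. Camera then called 0 chromosomes at day 0 without Pax7+/+ replicate 3 or Pax7-/- replicate 1 or 3, and 0 at day 21 without Pax7+/+ replicate 2. Array by array, chromosome 8 lay between -0.174 and -0.091 in the 9 Pax7+/+ arrays and between 0.074 and 0.196 in the 9 Pax7-/- arrays, and chromosome 11 between -0.191 and -0.070 and between 0.066 and 0.193. No other autosome and not the X chromosome separated the genotypes in this way, as the plot of chromosome medians shows. Of the genes called higher in Pax7-/-, 45 of 86, 44 of 71 and 314 of 847 lay on these chromosomes, against 12.1% of all genes. Genes are not independent, so no p-value is given. Of the genes given above as higher in Pax7-/-, Slc7a6, Cdh11, Herpud1, Mmp2, Sox1, Cyb5b, Abce1, Mcm5 and Tubb3 lie on chromosome 8, and Sparc, C1qbp, Npm1, Otx1, Top2a and Rpl19 on chromosome 11. Without the genes of both chromosomes the DNA replication, mitosis and ribosomal protein lists at day 21 had adjusted p = 2.89e-13, 4.43e-11 and 4.55e-08. The neural progenitor list kept its call (camera, adjusted p = 0.000116), and the trophoblast and Wnt target lists lost theirs (adjusted p = 0.0972 and 0.142). Without the genes of both chromosomes, 209, 78 and 668 genes differed between genotypes, and the share higher went from 30.3% to 17.7% at day 0 and from 51.1% to 28.2% at day 7. The 318 genes within 10 Mb of Pax7 on chromosome 4 were lower as a group at day 7 by camera (adjusted p = 0.008, and adjusted p = 0.114 with an estimated correlation), with 4 lower and 0 higher. At days 0 and 21 they did not pass (adjusted p = 0.673 and 0.625). The set depended on its width: the 50 genes on each side had adjusted p = 0.0714, 0.252 and 0.0469 at days 0, 7 and 21, and 0.384, 0.454 and 0.475 with an estimated correlation.

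**Figure D3:**
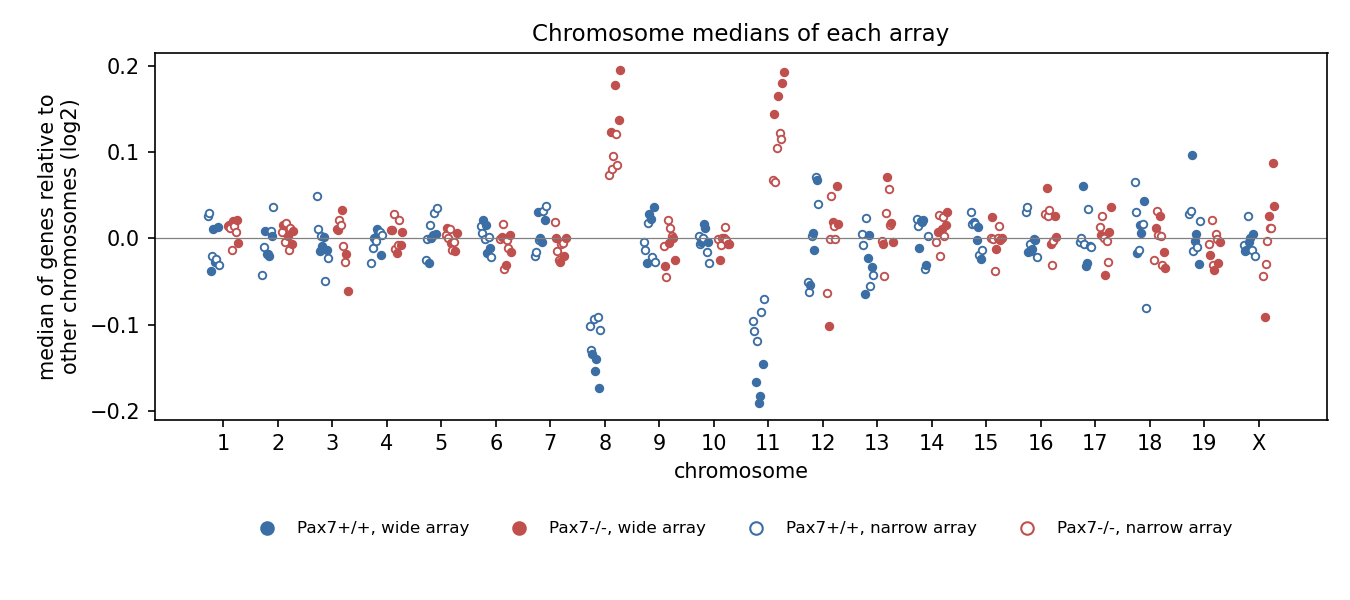
Median log2 value of the genes of each chromosome above the 75th percentile of mean log2 value in each array, each gene centred within its array set and each array on its other chromosomes; each point is 1 array, colour gives genotype, and filled or open points are wide or narrow arrays. Chromosomes 8 and 11 lie between 0.066 and 0.196 in the Pax7-/- arrays and between -0.191 and -0.070 in the Pax7+/+ arrays.

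The Y chromosome genes Eif2s3y and Uty were higher in every Pax7-/- array than in every Pax7+/+ array of the same set, and Kdm5d was so on the wide arrays and not on the narrow ones. On the wide arrays Eif2s3y read 7.09 to 7.69 log2 in 4 Pax7-/- arrays and 3.37 to 3.86 in 4 Pax7+/+ arrays, and Uty read 6.86 to 7.02 and 3.13 to 3.47. On the narrow arrays the genotypes lay closer, with Eif2s3y at 4.48 to 4.88 and 4.0 to 4.40 in 5 arrays each, and Uty at 3.81 to 4.0 and 3.42 to 3.74. Kdm5d read 3.67 to 5.16 in Pax7-/- and 3.30 to 3.41 in Pax7+/+ on the wide arrays, and 3.93 to 4.2 and 3.92 to 4.24 on the narrow arrays, where the genotypes overlapped. The list of 3 male-specific Y genes had adjusted p = 0.343, 0.0174 and 0.00783 at days 0, 7 and 21, and adjusted p = 0.966, 0.424 and 0.306 with an estimated correlation, with 0, 2 and 3 genes higher when adjusted over the list alone. Without the block camera called it higher at each day (adjusted p = 0.0258, 0.00731 and 0.000141, and 0.523, 0.422 and 0.155 with an estimated correlation). Xist, the RNA that coats an inactive X chromosome, did not pass between genotypes at any day. In Pax7+/+ Xist fell by 2.18 from day 0 to day 7 (SE 0.52, adjusted p = 0.0215), and in Pax7-/- the change was -1.23 ± 0.51 (adjusted p = 0.235).

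As the Pax7+/+ cells formed embryoid bodies, from day 0 to day 7, Lama1 rose by 4.50 ± 0.20 log2 (SE, n = 3 per day, adjusted p = 3.93e-09), or 22.6-fold, with Cubn (4.30 ± 0.43), Srgn (3.51 ± 0.16) and the retinol receptor gene Stra6 (2.21 ± 0.34). Also higher were the imprinted growth factor gene Igf2 (2.51 ± 0.30), Pramel20 (2.64 ± 0.38) and the 2-cell-like genes Zscan4e and Zscan4b (4.22 ± 0.67 and 3.48 ± 0.64). The chemokine genes Ccl2 and Ccl7 changed by -4.87 ± 0.45 and by -4.12 ± 0.49, the collagenase gene Mmp13 by -4.50 ± 0.63 and the BMP inhibitor gene Grem1 by -3.69 ± 0.44. Ptgs2 changed by -4.52 ± 0.33, Tnc by -4.09 ± 0.32 and Tm4sf1 by -2.29 ± 0.30. Without the block limma called 15 genes (9 higher and 6 lower, all at least 2-fold), Lama1, Srgn, Pramel20, Igf2, Stra6, Ccl2, Mmp13, Ccl7, Grem1 and Tm4sf1 among them. With it 1261 genes passed, 564 higher and 697 lower, 424 of them at least 2-fold. The 1261 became 612, 691 and 640 without Pax7+/+ day 0 replicate 3, day 7 replicate 2 and day 7 replicate 3.

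Parietal endoderm genes rose in Pax7+/+, 13 of 15 higher, 0 lower and 2 not passing (adjusted over the list alone, 14 higher and 1 lower; adjusted p = 1.1e-24, and adjusted p = 0.000153 with an estimated correlation). Gata6 came to 3.17 ± 0.28, Lamb1 to 3.16 ± 0.22 and Sox7 to 2.30 ± 0.32. Immediate early genes fell, 7 of 17 lower, 0 higher and 10 not passing (adjusted over the list alone, 11 lower; adjusted p = 3.78e-08, and adjusted p = 0.0138 with an estimated correlation). Fosb came to -1.50 ± 0.25 and Egr1 to -1.39 ± 0.13. Naive pluripotency genes were lower in 7 of 26 cases and higher in 1 (adjusted over the list alone, 1 higher and 10 lower; adjusted p = 8.16e-07, and adjusted p = 0.196 with an estimated correlation). Nr0b1 came to -2.92 ± 0.45, Tdgf1 to -1.67 ± 0.31 and Klf4 to -1.43 ± 0.16. Fibroblast genes were lower in 6 of 21 cases and higher in 2 (adjusted over the list alone, 2 higher and 13 lower; adjusted p = 2.21e-06, and adjusted p = 0.2 with an estimated correlation). Lox came to -3.09 ± 0.45 and Dcn to -3.05 ± 0.31. Here too a change in the share of fibroblasts cannot be told from a change within the cells. Retinoic acid response genes rose in 6 of 13 cases (adjusted over the list alone, 9 higher and 1 lower; adjusted p = 8.6e-06, and adjusted p = 0.2 with an estimated correlation), with Cyp26a1, the enzyme that clears retinoic acid, at 2.52 ± 0.38 and Meis2 at 1.4 ± 0.30. Visceral endoderm genes Cubn, Dab2 (2.43 ± 0.15) and Amn (1.45 ± 0.33) were the 3 of 24 that passed, all higher (adjusted over the list alone, 8 higher; adjusted p = 1.63e-06, and adjusted p = 0.33 with an estimated correlation). Interferon response genes fell in 5 of 16 cases, with B2m at -2.50 ± 0.28 (adjusted over the list alone, 9 lower; adjusted p = 8.6e-06, and adjusted p = 0.122 with an estimated correlation).

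Other lists moved in Pax7+/+ over this first step without holding with an estimated correlation. The 2-cell-like list rose, with Zscan4c, Tdpoz3 and Zscan4d passing among 11 (adjusted over the list alone, 10 higher; adjusted p = 2.71e-08, and adjusted p = 0.122 with an estimated correlation). Trophoblast genes rose as well, with Esx1 (1.28 ± 0.24), Cited1 and Krt7 passing among 12 (adjusted over the list alone, 5 higher; adjusted p = 8.6e-06, and adjusted p = 0.112 with an estimated correlation). Hypoxia and glycolysis genes rose in 6 of 14 cases, with the glucose transporter gene Slc2a1 at 1.16 ± 0.19 (adjusted over the list alone, 7 higher and 1 lower; adjusted p = 0.000904, and adjusted p = 0.275 with an estimated correlation). Imprinted genes rose in 6 of 22 cases and fell in 3, with Peg3 at 2.16 ± 0.18 and Peg10 at 1.52 ± 0.14 (adjusted over the list alone, 8 higher and 3 lower; adjusted p = 0.000904, and adjusted p = 0.33 with an estimated correlation). Hox genes rose in 3 of 36 cases and fell in 1 (adjusted over the list alone, 9 higher and 2 lower; adjusted p = 0.000478, and adjusted p = 0.33 with an estimated correlation). DNA replication genes fell in 5 of 19 cases, with Mcm3 at -0.84 ± 0.16 (adjusted over the list alone, 9 lower; adjusted p = 5.64e-06, and adjusted p = 0.112 with an estimated correlation). Without the block their direction was the other one (median 0.12 against -0.40 log2 with the block, adjusted p = 0.471). Smooth muscle genes Acta2 (-2.06 ± 0.24), Tagln (-1.39 ± 0.18) and Cnn1 (-1.14 ± 0.17) fell among 11 (adjusted over the list alone, 3 lower; adjusted p = 0.0307, and adjusted p = 0.33 with an estimated correlation). Rpl7 fell (-0.72 ± 0.17, against 0.10 without the block) among 15 ribosomal protein genes (adjusted over the list alone, 2 lower; adjusted p = 0.0242, and adjusted p = 0.196 with an estimated correlation). That list did not pass after quantile normalization (median -0.07, adjusted p = 0.257), and without the block it went the other way (median 0.10, adjusted p = 0.76).

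In Pax7-/- the step from day 0 to day 7 brought rises of Fabp7, a fatty acid binding protein gene of radial glia (3.16 ± 0.61 log2, SE, n = 3 per day, adjusted p = 0.00689, 8.96-fold), of the fetal serum protein gene Afp (2.99 ± 0.62), of the imprinted gene Peg3 (2.72 ± 0.18), of the tissue factor gene F3 (2.66 ± 0.23) and of Car4 (2.48 ± 0.34). The pluripotency genes Nr0b1 and Zfp296 changed by -3.50 ± 0.44 and by -3.47 ± 0.27. Mmp13 changed by -3.09 ± 0.62, Jam2 by -2.68 ± 0.17 and the matrix gene Bgn by -2.63 ± 0.32. Naive pluripotency genes fell in 15 of 26 cases and rose in 0, with 11 not passing (adjusted over the list alone, 22 lower; adjusted p = 1.47e-21, and adjusted p = 0.0309 with an estimated correlation). Nanog came to -1.92 ± 0.32, Tdgf1 to -1.84 ± 0.30 and Zfp42 to -1.72 ± 0.37. Parietal endoderm genes rose in 10 of 15 cases and fell in 0 (adjusted over the list alone, 14 higher; adjusted p = 1.19e-20, and adjusted p = 0.000384 with an estimated correlation). Lamb1 came to 2.34 ± 0.22, Lama1 to 2.20 ± 0.20 and the collagen gene Col4a2 to 2.08 ± 0.26. DNA replication genes fell in 7 of 19 cases (adjusted over the list alone, 9 lower; adjusted p = 5.35e-08, and adjusted p = 0.0475 with an estimated correlation). Mcm4 came to -0.87 ± 0.18 and Pcna to -0.79 ± 0.15. Retinoic acid response genes rose in 5 of 13 cases and fell in 1 (adjusted over the list alone, 9 higher and 1 lower; adjusted p = 6.83e-07, and adjusted p = 0.281 with an estimated correlation). Cyp26a1 came to 2.18 ± 0.37. Visceral endoderm genes Afp, Apoa1 (2.07 ± 0.52) and Dab2 (1.49 ± 0.15) rose among 24 (adjusted over the list alone, 8 higher; adjusted p = 5.24e-09, and adjusted p = 0.443 with an estimated correlation). The hypoxia, imprinted, Hox and neural progenitor lists rose and the mitosis list fell (adjusted p = 5.42e-06, 0.000146, 0.000164, 0.0154 and 0.0345), with adjusted p = 0.252 to 0.865 with an estimated correlation. The mitosis list did not pass after quantile normalization (adjusted p = 0.0594) or without the block (adjusted p = 0.426). Without the block limma called 0 genes for this step, and 354 at an unadjusted p under 0.05. With it 857 passed, 454 higher and 403 lower, 228 at least 2-fold. The 857 became 429 without Pax7-/- day 0 replicate 2, and 476, 506 and 530 without day 7 replicates 1, 2 and 3.

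From day 7 to day 21 in Pax7+/+, Gkn2 and Gkn1, which encode secreted gastrokines of the stomach lining, rose by 5.55 ± 0.41 and 4.18 ± 0.42 log2 (SE, n = 3 per day, adjusted p = 2.4e-06 and 3.58e-05), or 47-fold and 18.1-fold. Chil1 (2.96 ± 0.48), the matrix gene Dcn (2.84 ± 0.31) and Igfbp5 (2.80 ± 0.50) rose as well. Zscan4e changed by -4.62 ± 0.67, Zscan4b by -3.54 ± 0.64, Nanog by -3.52 ± 0.33, Dppa2 by -3.47 ± 0.34 and Pramel19 by -3.34 ± 0.65. Without the block limma called 5 genes (2 higher and 3 lower), Gkn2, Gkn1, Tmem92 (-2.11 ± 0.23 with the block) and D13Ertd608e (-1.11 ± 0.12) among them. With it 1297 genes passed, 304 higher and 993 lower, 292 at least 2-fold. Without Pax7+/+ day 7 replicates 2 and 3, each left out alone, 673 and 679 passed. Quantile normalization moved the share higher from 23.4% to 34.8%.

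Mitosis genes fell in 17 of 20 cases in Pax7+/+ from day 7 to day 21 and rose in 0 (adjusted over the list alone, 20 lower; adjusted p = 2.63e-21, and adjusted p = 0.00611 with an estimated correlation). Ccna2 came to -1.19 ± 0.22 and Plk1 to -1.10 ± 0.21. Naive pluripotency genes fell in 12 of 26 cases and rose in 1 (adjusted over the list alone, 1 higher and 19 lower; adjusted p = 1.33e-17, and adjusted p = 0.0259 with an estimated correlation). Nr0b1 came to -3.25 ± 0.45 and Tdgf1 to -3.16 ± 0.31 beside Nanog. DNA replication genes fell in 7 of 19 cases (adjusted over the list alone, 16 lower; adjusted p = 8.46e-13, and adjusted p = 0.00611 with an estimated correlation), with Mcm5 at -1.32 ± 0.18. Ribosomal protein genes fell in 6 of 15 (adjusted over the list alone, 11 lower; adjusted p = 4.94e-08, and adjusted p = 0.00611 with an estimated correlation). Rpl10a came to -0.90 ± 0.13. Immediate early genes rose in 8 of 17 cases and fell in 1 (adjusted over the list alone, 10 higher and 1 lower; adjusted p = 1.15e-08, and adjusted p = 0.00611 with an estimated correlation). Egr1 came to 2.25 ± 0.13 and Fos to 2.12 ± 0.29. Fibroblast genes rose in 7 of 21 cases (adjusted over the list alone, 11 higher; adjusted p = 1.22e-08, and adjusted p = 0.143 with an estimated correlation). Postn came to 2.45 ± 0.44, Col1a2 to 2.11 ± 0.41 and Col1a1 to 1.84 ± 0.33. On narrow and wide arrays these were 1.18 and 3.9, 0.64 and 3.55, and 1 and 2.72. The 2-cell-like list fell in 5 of 11 cases (adjusted over the list alone, 8 lower; adjusted p = 7.65e-08, and adjusted p = 0.143 with an estimated correlation). Zscan4d came to -2.60 ± 0.41. Smooth muscle, parietal endoderm, neural progenitor, Notch, interferon and blood lists rose and Hox, germ line and retinoic acid lists fell, with adjusted p between 4.57e-05 and 0.0144, and with adjusted p = 0.157 to 0.446 with an estimated correlation. Without the block the parietal endoderm and Notch lists did not pass (adjusted p = 0.755 and 0.277), and camera gave parietal endoderm the other direction. Cardiac muscle genes were higher as a list with 0 of 25 passing, adjusted over the list alone included (adjusted p = 5.75e-05, and adjusted p = 0.39 with an estimated correlation).

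In Pax7-/- the same step raised Gkn2 by 4.42 ± 0.41 and Gkn1 by 3.90 ± 0.42 log2 (SE, n = 3 per day, adjusted p = 0.000113 and 0.000333), or 21.5-fold and 14.9-fold, and Sox1 by 2.19 ± 0.26. Thbs1 (2.37 ± 0.18), the forebrain gene Fezf1 (2.30 ± 0.50) and Prtg (2.23 ± 0.48) rose too. On narrow and wide arrays Fezf1 rose by 0.7 and 3.53, Thbs1 by 2.23 and 2.28 and Prtg by 2.44 and 1.82. Cubn changed by -2.87 ± 0.43, Cyp26a1 by -2.35 ± 0.38, Tdgf1 by -1.86 ± 0.31, Dppa2 by -1.79 ± 0.34 and Npl by -1.57 ± 0.27. Neural progenitor genes rose in 5 of 20 cases and fell in 0 (adjusted over the list alone, 14 higher; adjusted p = 2.28e-13, and adjusted p = 0.202 with an estimated correlation). Otx1 came to 1.77 ± 0.34, Emx2 to 1.23 ± 0.27 and Pax6 to 0.85 ± 0.18. On narrow and wide arrays these were 0.67 and 2.53, 0.39 and 1.81, and 0.41 and 1.11. Jag1 (1.36 ± 0.17), Lfng (1.32 ± 0.25) and Hes1 (1.01 ± 0.21) rose among 14 Notch pathway genes (adjusted over the list alone, 5 higher; adjusted p = 1.11e-07, and adjusted p = 0.202 with an estimated correlation). Hoxb9 changed by -1.45 ± 0.24 among 36 Hox genes (adjusted over the list alone, 9 lower; adjusted p = 3.28e-11, and adjusted p = 0.202 with an estimated correlation). Naive pluripotency genes fell in 3 of 26 cases (adjusted over the list alone, 2 higher and 7 lower; adjusted p = 1.29e-08, and adjusted p = 0.202 with an estimated correlation). Visceral endoderm, germ line, retinoic acid and parietal endoderm lists fell and cardiac muscle, DNA replication, adipocyte, primed epiblast, immediate early and smooth muscle lists rose, with adjusted p between 5.19e-07 and 0.0445, and with adjusted p = 0.202 to 0.449 with an estimated correlation. The smooth muscle list did not pass after quantile normalization (adjusted p = 0.0728), and the primed epiblast, parietal endoderm and adipocyte lists did not without the block (adjusted p = 0.18, 0.637 and 0.455). Without the block limma called 3 genes, Gkn2, Gkn1 and Sox1. With it 185 passed, 101 higher and 84 lower, 63 at least 2-fold. Each of the 6 Pax7-/- arrays moved this count: without day 7 replicates 1, 2 and 3 it was 71, 70 and 84, and without day 21 replicates 1, 2 and 3 it was 548, 102 and 46.

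The genotypes differed in how far some genes moved. From day 0 to day 7 the difference between genotypes changed for 107 genes with the block (84 at least 2-fold), from day 7 to day 21 for 202 and from day 0 to day 21 for 412, and for 0, 0 and 0 without it (limma, 184, 399 and 260 at an unadjusted p under 0.05). These counts rested on single arrays. The 107 became 213, 55 and 49 without Pax7+/+ day 7 replicates 1, 2 and 3, 59 without Pax7+/+ day 0 replicate 1, 63 and 64 without Pax7-/- day 0 replicates 1 and 3, and 60 and 57 without Pax7-/- day 7 replicates 1 and 3. The 202 became 129, 68 and 73 without Pax7+/+ day 7 replicates 1, 2 and 3, 307 and 96 without Pax7+/+ day 21 replicates 2 and 3, 64 and 80 without Pax7-/- day 7 replicates 1 and 2, and 96, 134 and 102 without Pax7-/- day 21 replicates 1, 2 and 3. The 412 became 188 and 269 without Pax7+/+ day 0 replicates 1 and 2, 254 and 270 without Pax7-/- day 0 replicates 1 and 3, and 257 without Pax7-/- day 21 replicate 2. Over the first step the Pax7-/- minus Pax7+/+ difference rose by 3.08 ± 0.62 log2 for Ccl2, 2.81 ± 0.44 for Tnc, 2.58 ± 0.47 for Ptgs2, 2.51 ± 0.24 for Cdh11 and 2.17 ± 0.29 for Herpud1. It changed by -4.76 ± 0.94 for Zscan4e, by -3.07 ± 0.58 for Zscan4d, by -2.86 ± 0.39 for Zfp296, by -2.83 ± 0.53 for Pramel20 and by -2.37 ± 0.33 for Tmem92. Over the second step it rose for Nanog (2.62 ± 0.48), Pramel20 (2.49 ± 0.54), Scd1 (2.15 ± 0.40), Terc (1.77 ± 0.35) and Dnmt3b (1.72 ± 0.29). It fell for Dcn (-2.27 ± 0.44), F3 (-2.0 ± 0.34), Ccn1 (-1.93 ± 0.29), Epas1 (-1.79 ± 0.24) and Slco2a1 (-1.76 ± 0.23). Between day 0 and day 21 it rose for Ptgs2 (2.21 ± 0.47), Chac1 (2.18 ± 0.42), Dnmt3b (1.95 ± 0.28), Taf1d (1.93 ± 0.47) and Cth (1.92 ± 0.29). It fell for Lama1 (-3.60 ± 0.28), Cubn (-2.82 ± 0.61), Srgn (-2.46 ± 0.22), Tmem64 (-2.38 ± 0.17) and Lamb1 (-2.32 ± 0.31).

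Several lists moved apart between the genotypes. Immediate early genes gained in Pax7-/- relative to Pax7+/+ over the first step, with a median of 0.81 log2 and Dusp1 (1.62 ± 0.24), Egr1 (1.17 ± 0.18) and Atf3 (1.04 ± 0.19) passing among 17 (adjusted over the list alone, 8 higher; adjusted p = 1.37e-08, and adjusted p = 0.0224 with an estimated correlation). Relative to Pax7+/+ they lost over the second step, with a median of -0.59 (adjusted over the list alone, 1 higher and 5 lower). By camera this change had adjusted p = 1.09e-06, and adjusted p = 0.0165 with an estimated correlation. Within Pax7+/+ and Pax7-/- their medians over that step were 0.62 and 0.15. Over the second step mitosis and DNA replication genes gained in Pax7-/- relative to Pax7+/+, each with a median of 0.68. Passing were 4 of 20 and 6 of 19 (adjusted over the list alone, 15 and 11 higher). By camera these lists had adjusted p = 4.42e-17 and 4.29e-16, and adjusted p = 0.0149 and 0.00922 with an estimated correlation. Ribosomal protein genes gained 0.43 relative to Pax7+/+ (adjusted over the list alone, 2 higher). By camera they had adjusted p = 2.93e-06, and adjusted p = 0.0149 with an estimated correlation. Within Pax7+/+ the medians of mitosis, DNA replication and ribosomal protein genes over that step were -0.66, -0.47 and -0.44. Within Pax7-/- they were -0.08, 0.20 and -0.03. The difference for parietal endoderm genes changed by -0.60 (adjusted over the list alone, 6 lower). By camera it had adjusted p = 2.93e-06, and adjusted p = 0.0165 with an estimated correlation. Without the block the immediate early and parietal endoderm lists did not pass over the second step and camera gave them the other direction (medians -0.02 and 0.10, adjusted p = 0.951 for both). Between day 0 and day 21 the parietal endoderm median changed by -1.11, with Lama1, Lamb1 and Gata6 (-1.99 ± 0.39) among the 5 of 15 passing (adjusted over the list alone, 9 lower; adjusted p = 1.53e-10, and adjusted p = 0.00851 with an estimated correlation). Over the same span DNA replication, mitosis and ribosomal protein genes gained 0.67, 0.56 and 0.39 relative to Pax7+/+ (adjusted over the list alone, 11, 13 and 9 higher). By camera these had adjusted p = 3.16e-12, 3.15e-12 and 1.14e-06, and adjusted p = 0.00995, 0.0303 and 0.00995 with an estimated correlation. Over the first step the difference changed by a median of -1.31 for the 2-cell-like list and 0.78 for the fibroblast list (adjusted p = 3.87e-10 and 9.07e-09, and adjusted p = 0.195 and 0.217 with an estimated correlation), with Zscan4d and Dcn (2.08 ± 0.43) passing. The 2-cell-like median was 0.82 in Pax7+/+ and -0.13 in Pax7-/- over that step, and the fibroblast median -0.81 and 0.15, neither list passing in Pax7-/- (adjusted p = 0.253 and 0.695). Over the second step both differences went the other way, by medians of 0.59 and -0.62 (adjusted p = 0.000176 and 5.52e-07, and adjusted p = 0.375 and 0.218 with an estimated correlation). Between day 0 and day 21 the medians were -0.34 and 0.05 (adjusted p = 0.0236 and 0.859, and adjusted p = 0.691 and 0.964 with an estimated correlation).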

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

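Of the tests in this part, those on mislabelled arrays, on the state of differentiation and on the counts under other splits of the arrays without the set block were planned. All others were chosen only after the result was seen, among them the counts under other splits with the set block, a block added once the sets had been seen, and what the splits with many genes share.

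The genotype difference changed with time for several results, by a test of that change with the array set as a block. It changed for 107 genes from day 0 to day 7, 202 from day 7 to day 21 and 412 from day 0 to day 21. Leaving out 1 array at a time moved these counts to between 49 (without Pax7+/+ day 7 replicate 3) and 213 (Pax7+/+ day 7 replicate 1), 64 (Pax7-/- day 7 replicate 1) and 307 (Pax7+/+ day 21 replicate 2), and 188 (Pax7+/+ day 0 replicate 1) and 591 (Pax7+/+ day 21 replicate 2). Immediate early genes shifted by a median of 0.81 log2 over the first step and -0.59 over the second. Over the second step the parietal endoderm list shifted by -0.6 log2, DNA replication by 0.68, mitosis by 0.68 and ribosomal proteins by 0.43. Without the block the immediate early and parietal endoderm lists did not pass over the second step, with medians of -0.02 and 0.10. From day 0 to day 21 parietal endoderm shifted by -1.11, DNA replication by 0.67, mitosis by 0.56 and ribosomal proteins by 0.39.

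Other splits of the arrays bear on these counts. With the set block, chosen after the sets had been seen, 2 of 100 splits gave as many as the real 107 genes. For the real 412 genes it was 4 of 100, both shares under 0.05. The splits drew genotype anew within each day, which removes the genotype difference itself and not only its change. These shares therefore cannot exclude chance as the source of a change in the difference. The stricter condition written beforehand, that no other split give as many, was not met, the highest other splits giving 380 and 837. For the 202 genes 5 of 100 splits gave as many, the highest other 1603, so chance was not excluded. The splits with 380 and 837 genes kept the real genotypes at 1 day and exchanged them at the other, which adds the genotype differences of both days in place of comparing them, and over the second step the split of this kind gave 1120. The split with 1603 genes was the one in which the wide arrays were spread least evenly over the groups. Without the block 100, 100 and 100 of 100 splits gave at least the real 0, 0 and 0 genes, the highest others giving 15593, 17701 and 15453. These splits follow the array set: the 2, 1 and 4 splits with the wide arrays spread least evenly gave at least 15359, 17701 and 15004 genes, and all other splits at most 1, 4 and 17.

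For 3 arrays against 3 the 10 splits cannot give a share under 0.05. With the set block, 1 of 10 splits, the real one, gave as many genes in each of the 7 comparisons of groups. The real counts and highest others were 284 and 0, 139 and 51, and 1085 and 583 between genotypes at days 0, 7 and 21, 1261 and 6, and 1297 and 5 for the Pax7+/+ steps, and 857 and 0, and 185 and 27 for the Pax7-/- steps. Without the block, 10, 10 and 10 of 10 gave as many as the real 0, 0 and 0 genes at days 0, 7 and 21, with highest others of 0, 6 and 236. For the Pax7+/+ steps 1 of 10 gave as many as the real 15 (highest other 2) and 2 of 10 as many as the real 5 (highest other 12). For the Pax7-/- steps 10 of 10 gave as many as the real 0 (highest other 0) and 2 of 10 as many as the real 3 (highest other 24).

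The arrays of every group fell into 2 sets with different spread. The tables argue against genotype or day as the source, since 6 of 6 groups had arrays in both sets, and against mislabelled arrays, since 18 of 18 arrays matched best an array of their own group in the other set. An array-wide rescaling of 1 set before deposit would keep the order of genes, and the highest rank correlation between the sets was 0.798, against 0.902 or higher within a set. Open stay 2 rounds of RNA handling, hybridisation or summarising, which cannot be told apart, since the highest correlation between the sets within a group, 0.789, comes from the values by which the sets were found. No biological explanation outside the groups was tested.

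Genes of chromosomes 8 and 11 were higher in Pax7-/- at all 3 days. The tables argue against the state of differentiation, since the largest shift of either chromosome between days within a genotype was 0.052 log2, and against the array set, since the smallest shift between genotypes within a set was 0.189, where the largest of any other autosome was 0.067. Extra copies of both chromosomes in the Pax7-/- line are a candidate explanation: with each autosome divided into 5 segments, 30 of 30 segments of the 2 chromosomes over the 3 days lay above every segment of the other autosomes on the same day. Arrays give relative values, so they do not tell a gain in the Pax7-/- line from a loss in the Pax7+/+ line. Whether all cells carry such a change was not tested. A change of copies would add to the genotype differences apart from Pax7.

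The Y chromosome genes Eif2s3y and Uty were higher in Pax7-/- than in Pax7+/+ on both sets of arrays, and Kdm5d on the wide arrays. An XX Pax7+/+ line with X inactivation on differentiation would bring Xist up by day 21 and above Pax7-/-. Xist changed by -2.39 ± 0.51 log2 from day 0 to day 21 in Pax7+/+. Its day 21 means were 4.18 log2 in Pax7+/+ and 4.04 in Pax7-/-, which argues against that. The fall itself was not particular to Pax7+/+, since the Pax7-/- mean at day 0 was 5.56. A Y chromosome in the Pax7-/- line that the Pax7+/+ line lacks may explain the values and stays open. The smallest gap between genotypes within a set was 0.07 log2 for Eif2s3y and Uty, but -0.31 for Kdm5d, which overlapped on the narrow arrays, where it read 4.24 or lower in both genotypes. Male feeder or other fibroblasts in the Pax7-/- cultures stay open too. From day 0 to day 7 on the wide arrays the lowest change of a Y gene was -0.11, while Lox, the single gene of the fibroblast list that fell in Pax7-/-, changed by -3.4 on the same arrays (-1.71 ± 0.44 with the set block). With the set block Pdgfra (1.81 ± 0.29) and Tgfbi (1.65 ± 0.42) of the same list rose. The test rests on 1 falling gene and on 1 wide array per day, so it cannot decide. Whether the lines differ in more than Pax7 and these chromosomes cannot be read from RNA.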

How the results depend on the processing

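Added after the data were seen were the fits by array set, all alternatives to the fit with the array set as a block, and the removal of chromosomes 8 and 11. Counts of genes are given in a fixed order: Pax7-/- against Pax7+/+ at days 0, 7 and 21, Pax7+/+ from day 0 to day 7 and from day 7 to day 21, Pax7-/- over the same steps, and the change of the genotype difference from day 0 to day 7, day 7 to day 21 and day 0 to day 21. The value after these, where given, counts genes changed the same way between genotypes at all 3 days. Where a count moved, the cause was not tested, except that stricter thresholds and fewer arrays or genes lower counts by construction. Signal over background was not measured, so what it limits is not known.

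Without a block, the values as deposited gave 0, 0, 0, 15, 5, 0, 3, 0, 0, 0 and 0 genes. The array set as a block gave 284, 139, 1085, 1261, 1297, 857, 185, 107, 202, 412 and 9, the narrow arrays alone 238, 32, 523, 489, 496, 637, 90, 74, 155, 420 and 1 and the wide arrays alone 1142, 410, 1901, 3026, 3161, 3222, 815, 464, 337, 811 and 30. Where a set held 1 array of a group, the lone array was assumed to vary like the other groups. On the wide arrays both arms held 1 array for Pax7-/- against Pax7+/+ at day 0 and for Pax7-/- from day 0 to day 7, and in the other comparisons of 2 groups within a set at least 1 arm did, except on the narrow arrays for those same 2, so these counts support no result. Quantile normalization again gave 11, 7, 73, 225, 139, 115, 16, 12, 3, 10 and 1 genes, and median centring gave 0, 0, 0, 4, 4, 0, 2, 0, 0, 0 and 0. Filters at the 25th percentile and the median gave 0, 0, 0, 18, 7, 1, 3, 0, 0, 0 and 0, and 0, 0, 0, 18, 6, 1, 3, 0, 0, 0 and 0. Means of probe sets gave 0, 0, 0, 17, 5, 2, 3, 0, 0, 0 and 0, and every probe set tested alone gave 3, 8, 1, 44, 27, 0, 3, 0, 0 and 0. Trend and robust options gave 0, 1, 0, 11, 5, 0, 2, 0, 0, 0 and 0, no moderation 0, 1, 1, 8, 8, 0, 3, 0, 0, 1 and 0, and fits to the groups compared 0, 0, 0, 0, 1, 0, 0, 0, 0 and 0. An adjusted p under 0.01 gave 0, 0, 0, 2, 2, 0, 1, 0, 0 and 0, and treat against a 1.2-fold change 0, 0, 0, 12, 2, 0, 3, 0, 0 and 0. The replicate block gave 0, 0, 0, 47, 10, 1, 3, 0, 0, 0 and 0. Counts with array weights but without the set block are not given, since the estimate of the weights stopped before converging. An unconverged run had called far more genes before it was left out.

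With the array set as a block, quantile normalization gave 472, 242, 1370, 1428, 1486, 1356, 309, 209, 263, 564 and 22 genes and median centring 268, 150, 1088, 1320, 1327, 854, 209, 106, 158, 396 and 9. The filters gave 282, 134, 1099, 1289, 1318, 861, 193, 109, 195, 405 and 8, and 292, 145, 1129, 1315, 1379, 908, 208, 109, 194, 423 and 8. Means of probe sets gave 276, 136, 1035, 1240, 1252, 841, 180, 99, 196, 393 and 9, every probe set 233, 212, 1124, 1441, 1347, 810, 129, 123, 123 and 389, trend and robust options 277, 125, 1035, 1159, 1180, 812, 178, 98, 180, 406 and 8, and no moderation 183, 53, 784, 818, 914, 569, 99, 44, 99, 281 and 5. Array weights gave 399, 642, 1161, 1462, 1504, 964, 770, 258, 204, 658 and 27, and fits to the groups compared 313, 235, 653, 850, 695, 582, 90, 98, 169 and 131. An adjusted p under 0.01 gave 94, 20, 462, 564, 547, 357, 50, 40, 34 and 119, at least 2-fold 68, 37, 178, 424, 292, 228, 63, 84, 112 and 199, and treat 55, 5, 207, 383, 315, 223, 33, 41, 22 and 93. The replicate block beside the set block gave 238, 58, 856, 1123, 1000, 694, 105, 68, 73, 294 and 5. Without genes on chromosomes 8 and 11 the counts were 209, 78, 668, 1109, 1117, 689, 158, 92, 172, 348 and 5.

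Scaling moved some shares of genes higher by over 10 points. With the set block, quantile normalization gave 68.0% higher against 78.1% at day 21, 34.8% against 23.4% for Pax7+/+ from day 7 to day 21, and 63.9% against 79.2% for the genotype difference over that step. Without the block it gave 75% against 100% for Pax7-/- from day 7 to day 21, and median centring gave 75% against 60.0% for Pax7+/+ from day 0 to day 7.

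Leaving out 1 array at a time without a block gave 0 to 0, 0 to 9, 0 to 12, 2 to 76, 2 to 32, 0 to 1, 1 to 30, 0 to 2, 0 to 0, 0 to 0, 0 to 0 genes in the order above. Pax7+/+ day 7 replicate 1 gave the 9 at day 7, the 76 and 32 for the Pax7+/+ steps and the 2 for the genotype difference, and Pax7-/- day 21 replicate 1 the 12 at day 21 and the 30. Pax7-/- day 7 replicate 2 gave the 1 for Pax7-/- from day 0 to day 7. With the set block the ranges were 120 to 184, 21 to 242, 659 to 972, 612 to 1283, 673 to 1202, 429 to 784, 46 to 548, 49 to 213, 64 to 307, 188 to 591, 3 to 13. Every array of the 6 moved the counts at days 0 and 7 and for Pax7-/- from day 7 to day 21 by over 1.5 times. At day 21 Pax7-/- replicates 2 and 3 did (707 and 659). From day 0 to day 7 Pax7+/+ day 0 replicate 3 and day 7 replicates 2 and 3 did (612, 691 and 640), and from day 7 to day 21 Pax7+/+ day 7 replicates 2 and 3 (673 and 679). For Pax7-/- from day 0 to day 7 it was day 0 replicate 2 and day 7 replicates 1, 2 and 3 (429, 476, 506 and 530). The genotype difference moved with 8, 10 and 5 of the 12 arrays of its 3 comparisons, the extremes being Pax7+/+ day 7 replicates 3 and 1, Pax7-/- day 7 replicate 1 and Pax7+/+ day 21 replicate 2, and Pax7+/+ day 0 replicate 1 and day 21 replicate 2. The count of genes shared by the 3 days was 3 without Pax7+/+ day 7 replicate 2 or 3 or Pax7-/- day 7 replicate 3, 4 without Pax7-/- day 7 replicate 1 or 2, and 5 without Pax7-/- day 0 replicate 3.

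Gene lists shifted numbered 7, 15, 16, 15, 21, 14 and 18 without a block for the genotype and step comparisons, and 8, 9, 16, 15, 17, 10 and 15 with the set block. Under quantile normalization they numbered 7, 10, 16, 16, 22, 10 and 17, and 6, 9, 14, 14, 20, 9 and 18 with the set block. An estimated correlation gave 1, 0, 0, 5, 0, 4 and 0, and 0, 0, 4, 2, 5, 3 and 0 with the set block, fry 0, 0, 0, 5, 3, 0 and 0, and 2, 2, 6, 14, 10, 6 and 3, and ranks 3, 10, 15, 12, 22, 14 and 14, and 3, 7, 15, 14, 19, 12 and 11. The replicate block gave 7, 9, 16, 13, 21, 13 and 15, and 5, 9, 15, 14, 20, 10 and 16 with the set block. Leaving out 1 array gave 9 to 22, 10 to 13, 11 to 17, 12 to 15, 16 to 21, 9 to 20, 12 to 18 lists without a block, and 5 to 8, 7 to 13, 13 to 16, 13 to 16, 15 to 20, 8 to 12, 12 to 20 with the set block. Without genes on chromosomes 8 and 11 the set block gave 7, 10, 14, 15, 16, 10 and 13.

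Chromosomes shifted at days 0, 7 and 21 numbered 2, 2 and 1 without a block and 3, 3 and 2 with the set block, of the chromosomes and the region beside Pax7. Quantile normalization gave 3, 3 and 1, and 2, 3 and 2 with the set block, the 25th percentile filter 3, 2 and 1, and 3, 3 and 2, and the replicate block 3, 1 and 1, and 3, 3 and 2. An estimated correlation gave 1, 5 and 2, and 0, 2 and 0, fry 0, 0 and 2, and 2, 7 and 2, and ranks 3, 1 and 1, and 3, 3 and 2. Leaving out 1 array gave 0 to 1, 1 to 4, 0 to 2 without a block and 2 to 3, 2 to 3, 2 to 2 with it. Without a block Pax7+/+ day 0 replicate 3, Pax7-/- day 0 replicates 1 and 3 and Pax7+/+ day 21 replicate 2 each gave 0.

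The Pax7 difference passed in no setting. At day 0 it was 0.03 log2, and -0.04 on the wide arrays alone, with -0.42, -0.30 and -0.13 without Pax7+/+ replicate 3, Pax7-/- replicate 1 and Pax7-/- replicate 3, and at most 0.51. At day 7 it was 0.35, and -0.01 with the array set as a block and -0.26 on the narrow arrays alone, and 0.00 to 0.84 with 1 array left out. At day 21 it was -0.10, and 0.01 under median centring, 0.25 with the set block, 0.22 on the narrow arrays, and -0.33 to 0.10 with 1 array left out, with 0.10 without Pax7+/+ replicate 1 and 0.05 without Pax7-/- replicate 2. The first principal component held 79.7% of the variance, 71.8% after quantile normalization and 38.1% with the array set removed.

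The 252 pairs of a gene and a comparison named in the report had 5216 values under alternatives to the fit with the set block. Of these, 4268 kept direction and side of the threshold, 941 lost the call in the same direction, 6 gained one and 1 reversed, which was Rpl7 in Pax7+/+ from day 0 to day 7 with 0.10 log2 without the set block. The naming rule picked 616 further pairs that the report leaves out, 192 of them called with the set block. Of these, 7 had the other sign without it, none past the threshold there: Mcm6 (0.02) and Kif11 (0.05) for Pax7+/+ from day 0 to day 7, Mef2a (-0.15), Mef2d (-0.04) and Sgce (-0.03) from day 7 to day 21, Fbxo15 (0.17) for Pax7-/- over that step and Klf4 (0.05) for the genotype difference over it.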
